A study of Mus musculus with 6 samples.

How the data were processed

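RNA from 3 clonal lines derived from the mouse lymphoma line EL4 was labelled and hybridised to Affymetrix arrays. The lines were WT2, V7 and C5, and each gave 2 aliquots of cells handled in parallel, for 6 arrays. The cells were kept overnight without serum and otherwise left untreated. The lines differ in their labels. WT2 is sensitive to PMA, a phorbol ester, and is non-adherent and non-metastatic. V7 is PMA-resistant, adherent and metastatic, and C5 is PMA-resistant, adherent and highly metastatic.

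The deposited value table holds 1 linear signal intensity per probe set and array, made with MAS5 according to the submitters' processing notes, which state no version. The table has 45101 probe sets, of which 64 are array controls. All 6 arrays had the same 2% trimmed mean signal of 125, so each array had been scaled to that value by the authors. No array pair had identical values. Median signals ran from 15.8 to 21.5. The number of arrays, 2 per line, limits the precision of every value below.

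Gene names came from the deposited lists of probe sets that the authors reported as different, 1 list for V7 and WT2 and another for C5 and V7. Per the file headers, these hold a fold ratio, log2 means of each line and p-values of a t-test, raw and adjusted. The p-values of all 2420 and 102 listed probe sets were recomputed from the listed means and standard errors as an equal-variance test to within 0.001%. The 71 probe sets found in both lists had V7 log2 means that differed between the lists by a median of 0.22 and by up to 2.12, so the lists were summarised separately, in a way not given in the sources used here. The lists served for gene names and for a comparison of calls, and all tests below used the value table.

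Gene names existed only for the 2451 listed probe sets. Of these, 1937 carried a gene name (1510 genes), 507 an unplaced sequence entry and 7 a pair of different names. Another 42587 probe sets had no name. A symbol was added for 457 probe sets through their RefSeq accession, and 106 genes of the fixed lists were matched by hand from the deposited name. A full deposited name was accepted in place of a symbol, an interpretation made after the names had been seen. Named probe sets with probes shared between transcripts (254) were counted but left out of the rule for naming genes. Probe sets were the unit for all counts of calls. For a named gene the probe set with the highest mean signal stood for it. Genomic positions were not used here.

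Signals were analysed as log2(signal + 5.03), the added constant being the 25th percentile of all signals. Probe sets with a mean signal above the 40th percentile (11.7) were tested, 27022 in all. A linear model with 1 mean per line was fitted to all 6 arrays in limma 3.58.1 (R 4.3.3), with moderated variances that follow the mean signal (3 residual and 8.47 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 and a change of at least 2-fold. A gene that did not pass missed at least 1 of these limits, so some had a low adjusted p but changed by less than 2-fold. Tests were two-sided. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The labels do not say that the aliquots came from separate cultures, so p-values measure only the spread between aliquots, which may be technical, and the PMA-sensitive, non-adherent phenotype and each metastasis label are represented by 1 clone.

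The comparisons were V7 with WT2, C5 with V7 and C5 with WT2. Probe sets called the same way in V7 and C5 against WT2 were counted beside the number expected of independent lists and of 100 simulated sets of unchanged lines that share the WT2 arrays. Probe sets called the same way from WT2 to V7 and from V7 to C5 were counted as stepwise. The fit was tested on simulated data with 50 planted changes of each size. Between C5 and V7 it called 68%, 78%, 92% and 92% of planted 3-, 4-, 8- and 16-fold changes, with 3 false calls. Between V7 and WT2 it called 76%, 76%, 92% and 92%, with 7 false calls. The same number of changes was planted for both comparisons, unlike in the real data. These rates therefore do not show that both comparisons were equally open to calls.

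Gene lists for 19 pathways and 6 other cell types, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 3 named, tested members were compared with the other named genes by limma's camera with a preset correlation of 0.01, adjusted over all lists and the 3 comparisons. The background was the 1505 named genes tested. The authors had selected the named probe sets on these same samples for a difference, so counts of named genes and lists are not independent evidence of a difference. The rule named 90 genes: the 8 largest rises and falls for V7 with WT2 and for C5 with V7, the 5 largest for C5 with WT2, up to 4 called members per list, 12 genes tied to the study group's work on phorbol esters, focal adhesion kinases and lysophospholipids (5 with a named probe set) and 5 per direction for shared and stepwise calls. Of these, 2 are counted but not described here.

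The alternatives were an added constant of 1 or of the median signal (18.1), no signal filter (45037 probe sets) or one at the 60th percentile (30.1; 18015 probe sets), quantile normalization, variances without a trend, a term for the aliquot number, other thresholds, only the 2 lines compared, and leaving out each array. The methods' t-test was added after seeing the data.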

Results

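Transcript levels were measured on 6 Affymetrix mouse arrays in 3 clones of EL4, a mouse T lymphoma line, with 2 aliquots per clone. WT2 is labelled sensitive to PMA, a phorbol ester that mimics diacylglycerol and activates protein kinase C and RasGRP proteins. V7 and C5 are labelled PMA-resistant and adherent, and they differ in their metastasis label. Signals ran from 0.0209 to 19720 per array. The median signal was 20.9 ± 0.756 in WT2, 15.9 ± 0.0917 in V7 and 17.4 ± 0.620 in C5 (mean ± SD, n = 2 in each line). The aliquots of one line correlated across probe sets with r = 0.956 in WT2, 0.974 in V7 and 0.968 in C5. Arrays of V7 and C5 correlated with each other at 0.966 to 0.968, about as closely as the C5 aliquots. This was above the value of the WT2 aliquots and below that of the V7 aliquots. WT2 arrays correlated with V7 and C5 arrays at 0.876 to 0.892. The first principal component, with 64.0% of the variance, separated WT2 from V7 and C5. The second (10.95%) separated the 2 WT2 aliquots from each other. The control ratio of 3' to 5' signal of Gapdh was 1.64 ± 0.181 in WT2, 0.924 ± 0.0519 in V7 and 0.991 ± 0.229 in C5 (n = 2 each), so this sign of RNA or labelling quality moved with WT2. The same ratio of beta-actin was 1.93 ± 0.149, 2.27 ± 0.326 and 2.39 ± 0.741. The 3' signal of beta-actin was 15623 ± 826 in WT2, 8815 ± 33.4 in V7 and 8554 ± 63.1 in C5.

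The comparison of V7 with WT2 asked which transcripts separate a PMA-resistant, adherent, metastatic clone from a PMA-sensitive, non-adherent, non-metastatic one. V7 had almost lost the transcript deposited as V-myc myelocytomatosis viral related oncogene, neuroblastoma derived (avian), the MYC family transcription factor Mycn. Its signal was 13376 ± 472 in WT2 and 31.1 ± 17.6 in V7 (n = 2 each; log2 change −8.62, SE 0.28, limma adjusted p = 2.89e-09). Other large falls were in Immunoresponsive gene 1, the enzyme that makes itaconate (−8.26), in the calcium-binding S100 calcium binding protein A6 (−7.90) and in the zinc importer Solute carrier family 39 member 4 (−7.66). They also included a regulatory subunit of cAMP-dependent protein kinase (type II alpha, −7.61), the mast cell protease Carboxypeptidase A3 (−7.49), the T cell adaptor FYN binding protein (−7.40) and SplA/ryanodine receptor domain and SOCS box containing 4 (−7.31). The largest named rises were in WNT1 inducible signaling pathway protein 1, a secreted matrix-associated protein, which went from 3.81 ± 4.16 to 3321 ± 179 (log2 change 8.64, SE 0.25, adjusted p = 1.14e-09), and in the milk protein Casein kappa (8.64). The granule protease Cathepsin G rose by 8.61 and the homeobox gene Reproductive homeobox 5 by 8.17. Trat1, an adaptor of the T cell receptor complex, rose by 7.42. Hyaluronan and proteoglycan link protein 1, which stabilises the pericellular matrix, rose by 7.22, Phosphodiesterase 3B by 6.77 and Kelch-like 4 by 6.67. In all, 1430 probe sets were higher and 1955 lower in V7, 12.5% of the 27022 tested, with a median change of 2.97-fold. Of the 90 genes named, 19 had a mean signal below the constant added before taking logs in at least 1 line, among them many with the largest changes and Ccr7, Cd2, Cd6, Cd247, Dnajb9, Dusp4, Pdgfra and Prkd3 below. The size of their changes depends on that constant. After quantile normalization 1703 were higher and 1538 lower, 86.2% of the calls were kept in direction, and the median log2 change over all tested probe sets moved from −0.13 to 0.01.

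**Figure D1:**
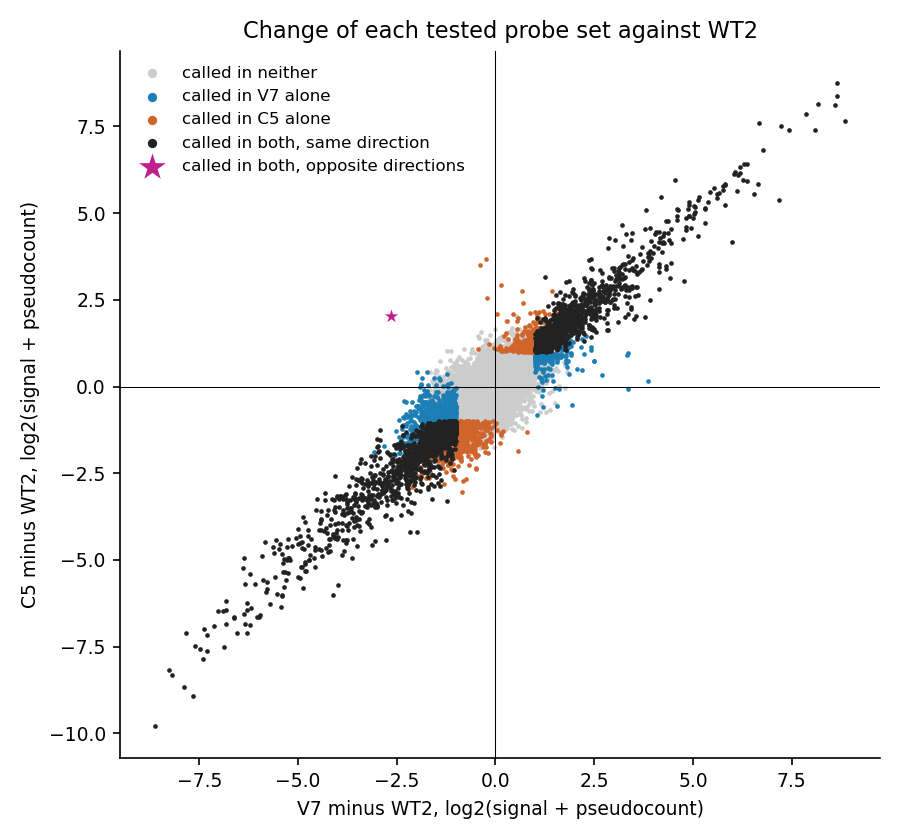
Each point is 1 of the 27022 probe sets tested, with the log2 change of V7 minus WT2 on the x axis and of C5 minus WT2 on the y axis. Black points were called the same way in both lines (1158 higher, 1467 lower), blue points in V7 alone, orange points in C5 alone, grey points in neither, and the star marks the probe set called in opposite directions.

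The named genes of the phorbol ester and diacylglycerol list were mostly lower in V7. This list also holds enzymes that act on diacylglycerol itself. Of its 31 genes, 12 had a named probe set, of which 11 fell and 1, Rasgrp2 (1.15), rose. Among all 1505 named genes tested, 632 rose, 600 fell and 273 did not pass. The falls were −6.29 on the log2 scale for Prkcb, a protein kinase C isoform, −4.93 for Plcg2, a phospholipase that makes diacylglycerol, −4.41 for the kinase Prkd3 and −3.10 for the diacylglycerol kinase Dgka. Rasgrp1, the Ras activator that binds phorbol esters, went from 2234 ± 17.7 in WT2 to 472 ± 20.8 in V7 (n = 2 each; log2 change −2.23, SE 0.12, adjusted p = 1.96e-07). Prkcq, the protein kinase C isoform of T cell receptor signalling, went from 334 ± 41.4 to 91.9 ± 2.16 (−1.80, SE 0.23, adjusted p = 1.46e-04). Of 25 genes on the list of ERK kinase targets, 7 had a named probe set, and 6 of these fell. The other, Phlda1, was lower (−0.72, limma adjusted p = 0.00238) but by less than 2-fold. Among the 6 were the transcription factor Etv5 (−4.75), the phosphatase Dusp4 (−3.53) and the ERK pathway inhibitors Spred2 (−2.93) and Spry1 (−2.25). Both lists were lower than the other named genes in camera with the preset correlation, at an adjusted p of 0.0143 for the phorbol ester list and 0.0287 for the ERK list. With an estimated correlation the adjusted p was 0.564 for both, so neither call held. The estimated correlations were −0.05 for the phorbol ester list and −0.11 for the ERK list. Both were below the preset value, so correlation among members did not by itself undo the calls. The probe sets with names had been picked by the authors for a difference between these samples, so these and all list counts that follow are not independent evidence, and they moved with the Gapdh 3' to 5' ratio of WT2, while that of beta-actin was lowest in WT2.

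**Figure D2:**
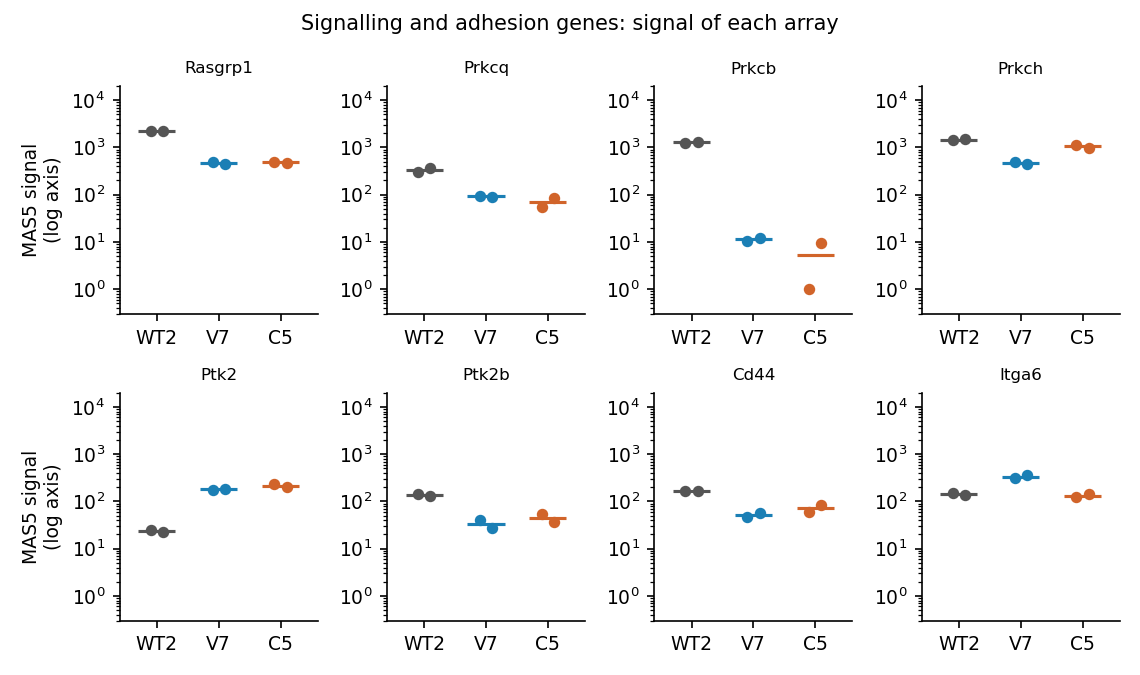
MAS5 signal on a log axis for each array of WT2, V7 and C5, for signalling genes (Rasgrp1, Prkcq, Prkcb, Prkch, Ptk2, Ptk2b) and the adhesion molecules Cd44 and Itga6. Points are aliquots and lines are means of 2 aliquots; Rasgrp1 was 2234 in WT2 against 472 in V7 and 491 in C5, while Ptk2 was 23.7 against 182 and 216.

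T cell surface and signalling genes went in different directions. Of 9 named T cell identity genes, 7 fell and 2 rose. Among those that fell were Cd2, an adhesion receptor of T cells (−6.63), Cd247, the zeta chain of the T cell receptor complex (−5.96), and the co-receptor Cd6 (−3.01), whereas Trat1 rose as given above. The Cd6 call did not hold without WT2 aliquot 1, where 1 WT2 array was left and the change was −2.74. The list did not pass camera (adjusted p = 0.280). Of 5 named genes of the Notch and early T cell list, 2 rose, 1 fell and 2 did not pass. Dntt, the polymerase that adds nucleotides during receptor gene rearrangement, rose by 5.99 and the lymphoid transcription factor Ikzf3 by 1.68. The Notch target Hes1 fell by 1.87, but its adjusted p was 0.101 without WT2 aliquot 1, 0.0626 without WT2 aliquot 2 and 0.133 without V7 aliquot 1.

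Focal adhesion genes also split, with the pair of focal adhesion kinases moving apart. Ptk2, focal adhesion kinase, went from 23.7 ± 2.03 in WT2 to 182 ± 4.30 in V7 (n = 2 each; log2 change 2.70, SE 0.20, adjusted p = 2.63e-06). Its relative Ptk2b went from 137 ± 10.8 to 34.1 ± 10.2 (−1.88, SE 0.28, adjusted p = 4.84e-04). Of the 8 named focal adhesion genes 3 rose and 5 fell, including the linker proteins Zyx (−2.58) and Lims1 (−1.86). Both named integrins rose, among them Itga6, a laminin receptor subunit (1.19). Of 6 other adhesion molecules 2 rose and 4 fell. Cd96, a receptor that binds nectin-family ligands, rose by 2.61, whereas Cd47, the ligand of SIRP alpha (−2.36), and the tetraspanin Cd81 (−1.35) fell. The hyaluronan receptor Cd44 went from 165 ± 2.59 to 52.6 ± 7.23 (−1.57, adjusted p = 5.13e-04). Of 5 matrix proteins and proteases 4 rose and 1 fell: the protease inhibitor Timp2 (1.34), the metalloprotease Adamts1 (1.30) and the lysosomal protease Ctsl (1.24) were higher, and osteopontin, Spp1, was lower (−1.61). The focal adhesion, other adhesion and matrix lists had an adjusted p of 0.681 each in camera, and integrins were too few to test.

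Receptors for soluble signals changed in both directions. Of 11 cytokines and their receptors 4 rose, 5 fell and 2 did not pass. The interleukin receptor subunits Il7r and Il27ra rose by 4.14 and 3.31 and the growth factor Tgfb3 by 3.01, whereas the tumour necrosis factor receptor Tnfrsf1b fell by 2.73. The camera direction of this list was down while its median (0.56) and mean (0.25) log2 change were positive. Both named chemokine receptors were lower, Cxcr6 (−1.69) and the lymph node homing receptor Ccr7 (48.5 in WT2 and 0.960 in V7; −3.16, a size that depends on the added constant). The Ccr7 call was lost without either WT2 aliquot (adjusted p of 0.0682 without aliquot 1 and 0.0563 without aliquot 2). In the lysophospholipid list the phosphatase Plpp2 fell by 3.95 and Sgpp1, which removes the phosphate of sphingosine 1-phosphate, rose by 1.13. The single named gene of the epithelial-mesenchymal list, the receptor Tgfbr2, fell by 2.01.

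Among growth and survival genes, 2 of 5 cell cycle genes rose, 1 fell and 2 did not pass. The inhibitor Cdkn1a rose by 2.29 and the inhibitor Cdkn2c fell by 1.40. The mitotic transcription factor Foxm1 rose by 1.16, which was 0.96 and below 2-fold without WT2 aliquot 1. Of 7 apoptosis genes 5 rose and 2 fell. The pro-apoptotic Bad (1.92) and Bid (1.27) were higher, as were the anti-apoptotic Bcl2a1a, Xiap and Bcl2. The caspase-8 regulator Cflar (−2.80) and Casp4 (−1.93) were lower. Of 9 interferon response genes 3 rose, 1 fell and 5 did not pass, with the GTPase Gbp3 (2.14), Usp18 (1.67) and Isg20 (1.31) higher and the RNA sensor Ddx58 lower (−1.32). Of 6 antigen presentation genes 5 rose and 1 fell. The class II chain H2-Eb1 rose by 3.98 and the immunoproteasome subunit Psmb10 by 1.57. H2-DMa rose by 1.57, although its adjusted p was 0.0608 without V7 aliquot 1, and the class I molecule H2-T23 fell by 1.27. Of 3 glycolysis genes 2 rose and 1 fell. The muscle-type phosphofructokinase Pfkm fell by 1.75 and Aldoc rose by 1.75 (adjusted p = 0.0429), which was 0.68 without WT2 aliquot 1 and lost its call without any single array except WT2 aliquot 2. Of 3 stress genes the sensor Atf6 rose by 1.92 on its brightest probe set and by 0.59 on another, below 2-fold, while the chaperone Dnajb9 (−5.01) and the folate enzyme Mthfd2 (−1.29) fell. No gene of the sterol and fatty acid synthesis list had a named probe set. No list other than the phorbol ester and ERK lists passed camera in this comparison. Counts for every list were the same when p-values were adjusted over the list alone.

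Markers of other cell types were largely without a named probe set, which was the case for all genes of the B cell, myeloid, epithelial and erythroid lists. The single named natural killer marker, the granule protease Gzma, rose by 1.78. Of 2 named fibroblast markers 1 rose and 1 fell, the receptor Pdgfra being higher by 3.46 (2.29 ± 0.582 to 75.9 ± 14.0). The marker that fell was Acta2, a smooth muscle actin, with 5987 ± 563 in WT2 and 49.6 ± 19.7 in V7 (log2 change −6.82). Its probe set has probes shared between transcripts, so the naming rule leaves it out.

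**Figure D3:**
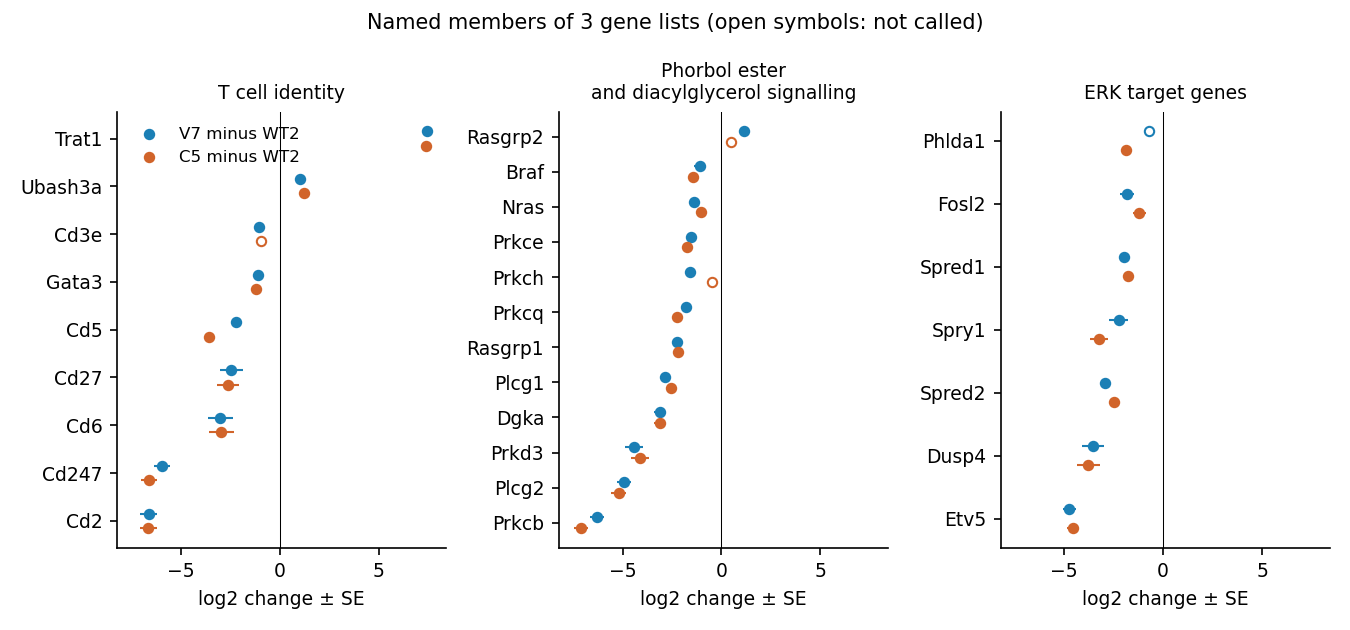
Log2 change with its standard error for the named members of the T cell identity, phorbol ester and diacylglycerol, and ERK target lists, in blue for V7 minus WT2 and in orange for C5 minus WT2. Open symbols were not called, as they changed by less than 2-fold, although each had a limma adjusted p below 0.05. In V7, 7 of 9, 11 of 12 and 6 of 7 members of these lists were called lower.

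The authors' own list for V7 and WT2 held 2420 probe sets, 1384 higher and 1036 lower in V7, with ratios from 2 to 453. Of these, 2411 were tested here, all had the same direction, and 2028 (84.1%) were called. The log2 changes correlated across these probe sets with r = 0.978, where probe sets are not independent replicates. A further 1357 called probe sets were outside that list. Of its probe sets, 105 had a deposited adjusted p above 0.05. The authors stated 2832 tests for this list and 141 for that of C5 and V7, so their adjustment did not cover the whole array.

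The comparison of C5 with V7 asked what separates a highly metastatic clone from a metastatic one, both adherent and PMA-resistant. Few transcripts differed. Leprecan-like 1, a collagen-modifying prolyl hydroxylase, went from 2.77 ± 1.15 in V7 to 194 ± 0.291 in C5 (n = 2 each; log2 change 4.68, SE 0.29, limma adjusted p = 3.28e-05), with 44.0 ± 4.55 in WT2. Its V7 signal was below the constant added before taking logs, so the size of this change depends on that constant: it was 5.73 with 1 added and 3.35 with the median signal added, and both passed. Regulator of G-protein signaling 18, which shortens signals from G protein-coupled receptors, went from 161 ± 12.02 to 2483 ± 231 (3.90, SE 0.18, adjusted p = 2.05e-06). Prkch, a protein kinase C isoform, was also higher in C5 (479 ± 34.7 to 1058 ± 105; 1.13, SE 0.13, adjusted p = 0.00595).

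Falls from V7 to C5 were found in the epithelial envelope protein Sciellin (−2.21, but −2.78 with 1 added and −1.40 with the median signal added) and in the lipid carrier Apolipoprotein D (−1.91). Dntt (−1.82), Fatty acid binding protein 4 (−1.76), Yippee-like 2 (−1.35) and the ERK target Phlda1 (−1.18) also fell, and Itga6 went from 334 ± 34.1 to 133 ± 14.8 (−1.29). Of 3 Dntt probe sets 2 passed and 1 did not (−1.42, limma adjusted p = 0.101). A second probe set of Fatty acid binding protein 4 did not pass either (−1.73, adjusted p = 0.0834). Both probe sets passed for Itga6 (−1.88 and −1.29), Prkch (1.13 and 1.17) and Regulator of G-protein signaling 18 (3.88 and 3.90). In list terms, Prkch was 1 of 12 phorbol ester genes, Phlda1 1 of 7 ERK targets, Itga6 1 of 2 integrins and Dntt 1 of 5 Notch and early T cell genes, and no member of the other lists passed. Adjusted over the list alone, 2 of 5 genes of the Notch list and 1 of 9 T cell identity genes passed as lower. Passing as higher were 1 of 2 chemokine genes, 1 of 11 cytokine genes and the 1 natural killer gene. In the shortest lists this adjustment does little, and with 1 gene it does nothing. No list passed camera, where the Notch list had an adjusted p of 0.280. The camera direction, median and mean differed in sign for the ERK (down, 0.18, −0.14), matrix (up, −0.03, 0.18) and cell cycle (up, −0.03, 0.04) lists. The genes of the study group's earlier interest did not pass: Rasgrp1 differed by 0.06 (adjusted p = 0.987), Ptk2 by 0.24 (0.930), Ptk2b by 0.36 (0.927), Prkcq by −0.42 (0.838) and Cd44 by 0.43 (0.850).

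In all, 8 probe sets were higher and 19 lower in C5 than in V7, 27 of 27022, with a median change of 2.70-fold. At an unadjusted p below 0.05 there were 1756, without a fold limit. The count depended on single arrays: it was 65 without WT2 aliquot 1, 68 without WT2 aliquot 2, 5 without either V7 aliquot, 6 without C5 aliquot 1 and 7 without C5 aliquot 2, and 4 without the variance trend. So did the excess of lower calls, as more were higher than lower without V7 aliquot 1 (5 and 0), V7 aliquot 2 (4 and 1), C5 aliquot 1 (4 and 2), C5 aliquot 2 (5 and 2) or the trend (3 and 1), with a term for the aliquot number (8 and 7) and at an adjusted p below 0.01 (7 and 6). Leprecan-like 1 and Regulator of G-protein signaling 18 stayed called with any array left out, although the latter had an adjusted p of 0.0553 without the trend. With a V7 or C5 array left out, 1 array remains in that line, so calls can also be lost because the test has less data. Of the 10 genes described, 8 lost the call without V7 aliquot 1 (adjusted p from 0.0941 to 0.327), 7 without V7 aliquot 2, 7 without C5 aliquot 1, 7 without C5 aliquot 2, 0 without either WT2 aliquot and 9 without the trend. Of the 1505 named genes tested, 16 were called between C5 and V7, 5 higher and 11 lower. Of these, 4 are read by probe sets with probes shared between transcripts, which the naming rule leaves out, and another 2, both lower in C5, are counted but not described here. The authors' list for this pair held 102 probe sets, 20 higher and 82 lower in C5. Of these, 100 were tested, all with the same direction here (r = 0.966 across probe sets), and 22 were called; 5 called probe sets were outside the list.

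**Figure D4:**
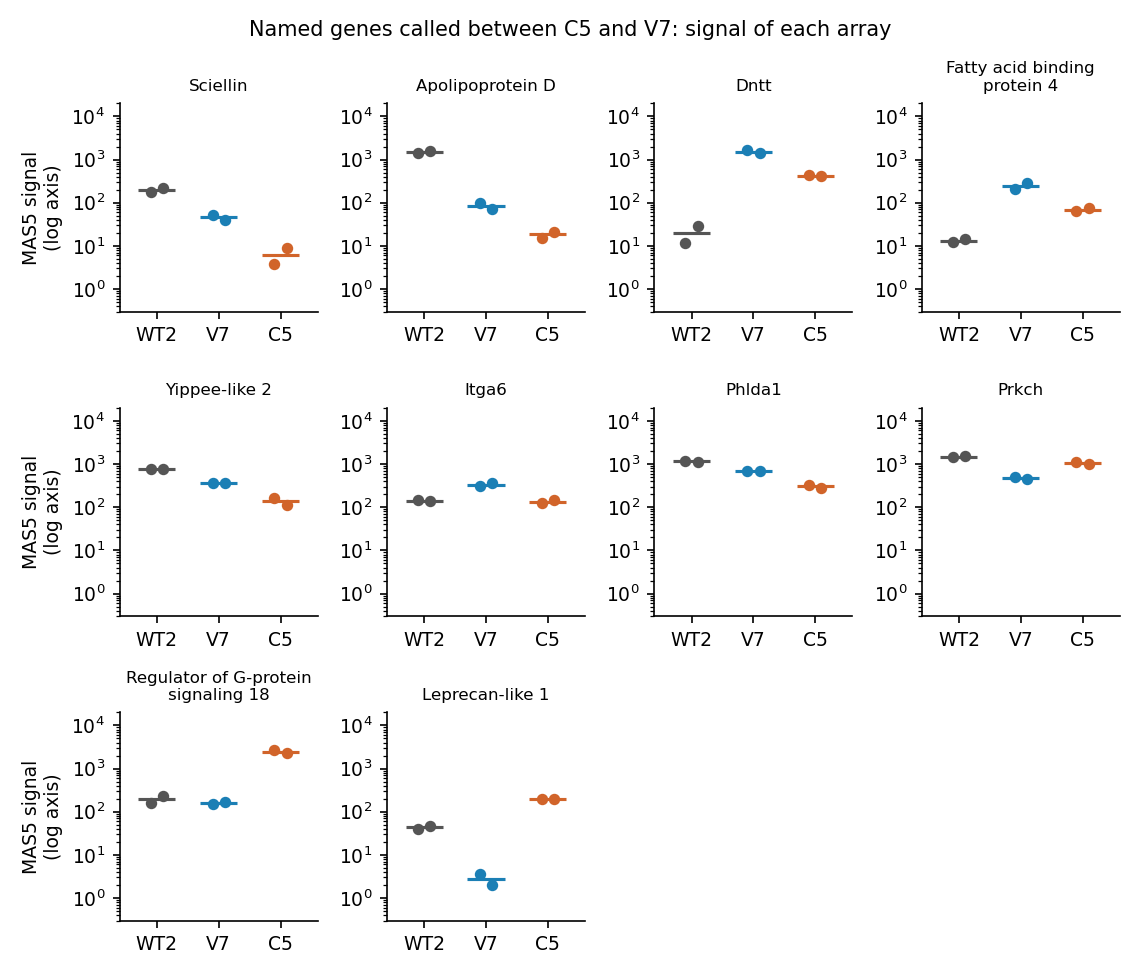
MAS5 signal on a log axis for each array of WT2, V7 and C5, for 10 of the 16 named genes called between C5 and V7. Points are aliquots and lines are means of 2 aliquots; Regulator of G-protein signaling 18 was 161 in V7 and 2483 in C5.

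The comparison of C5 with WT2, the third pair, gave 1509 probe sets higher and 2015 lower (13.0% of those tested). Mycn was again the largest named fall (10.2 ± 2.05 in C5, n = 2; log2 change −9.78, SE 0.28, adjusted p = 1.06e-09), followed by Solute carrier family 39 member 4 (−8.94), S100 calcium binding protein A6 (−8.66), Immunoresponsive gene 1 (−8.17) and FYN binding protein (−7.87). The largest named rises were in WNT1 inducible signaling pathway protein 1 (8.76), Casein kappa (8.38), Reproductive homeobox 5 (8.14), Cathepsin G (8.13) and Kelch-like 4 (7.59). Rasgrp1 (−2.17, SE 0.12, adjusted p = 2.41e-07), Prkcq (−2.23) and Ptk2b (−1.53, adjusted p = 0.00191) fell, and Ptk2 rose by 2.94. Cd44 fell by 1.14 (adjusted p = 0.00404), which was −0.90 and below 2-fold without C5 aliquot 1. Quantile normalization gave 1801 higher and 1744 lower, with 91.2% of the calls kept, and leaving out WT2 aliquot 1 gave 1962 higher and 1929 lower.

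Gene lists were counted for C5 as for V7, where 596 of all 1505 named genes rose in C5, 587 fell and 322 did not pass. In C5, 10 of the 12 named phorbol ester genes fell, among them Prkcb (−7.10), Plcg2 (−5.20), Prkd3 (−4.14) and Dgka (−3.13). Prkch (−0.47) and Rasgrp2 (0.50) passed the p limit but not the 2-fold limit. All 7 named ERK targets, of 25 on the list, fell, with Etv5 at −4.57, Dusp4 at −3.78, Spry1 at −3.25 and Spred2 at −2.51. These lists had camera adjusted p-values of 0.0143 and 0.0287, and 0.564 for both with an estimated correlation. Of 9 T cell genes 6 fell (Cd2 −6.65, Cd247 −6.60, Cd5 −3.58), 2 rose and 1 (Cd3e, −0.97) missed only the 2-fold limit. The T cell list had a camera adjusted p of 0.280. Of 8 focal adhesion genes 2 rose, 5 fell (Zyx −3.08, Lims1 −1.80, Fyn −1.70) and 1 did not pass. One of 2 integrins rose, and Itga6 changed by −0.10 without passing. Of 6 other adhesion molecules 1 rose (Cd96, 2.57), 4 fell (Cd47 −2.22, Cd81 −1.27) and 1 did not pass. Of 5 matrix genes 3 rose (Adamts1 1.76, Ctsl 1.22, Timp2 1.12) and 2 did not pass, where Timp2 was 0.90 without WT2 aliquot 2 and 0.91 without C5 aliquot 2. The Gapdh 3' to 5' ratio was lower in C5 than in WT2, as given above, and moved with these lists, while that of beta-actin was lowest in WT2.

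Of 11 cytokine genes 4 rose (Il27ra 4.40, Il7r 3.31, Tgfb3 2.66), 5 fell (the interferon gamma receptor Ifngr1, −2.82) and 2 did not pass. Ccr7 fell by 3.12, with adjusted p-values of 0.0692 and 0.0571 without WT2 aliquots 1 and 2, and the other chemokine receptor did not pass. Plpp2 fell by 3.23, Sgpp1 rose by 1.12 and Tgfbr2 fell by 1.79. Of 5 cell cycle genes 2 rose (Cdkn1a 2.34, Foxm1 1.48), 1 fell (Cdkn2c −1.47) and 2 did not pass. Of 7 apoptosis genes 4 rose (Bad 1.80), 2 fell (Cflar −2.76, Casp4 −1.99) and 1 did not pass. Bid rose by 1.07, but by 0.88 without WT2 aliquot 2 and 0.99 without C5 aliquot 1. The other risers were the anti-apoptotic Bcl2a1a and Xiap, and Bcl2 was the gene that did not pass. Of 9 interferon genes 3 rose (Gbp3 1.96, Isg20 1.54, Usp18 1.32), 1 fell (Ddx58 −1.17) and 5 did not pass. Of 6 antigen presentation genes 2 rose (H2-Eb1 3.86, Psmb10 1.98), 1 fell (H2-T23 −1.60) and 3 did not pass, with 4 called when adjusted over the list alone. Of 3 glycolysis genes 1 rose, 1 fell (Pfkm −1.80) and 1 did not pass, with 3 called when adjusted over the list alone; all other lists kept their count. Of 5 Notch and early T cell genes 2 rose (Dntt 4.17, Ikzf3 1.42), 2 fell and 1 did not pass. Those that fell were Hes1 (−2.01; adjusted p = 0.0756 without WT2 aliquot 1 and 0.106 without C5 aliquot 1) and Id3 (−1.57; 0.0870 without WT2 aliquot 1 and 0.123 without C5 aliquot 1). Atf6 rose by 2.22, but by 0.67 on its other probe set, while Dnajb9 (−5.50) and Mthfd2 (−1.47) fell. No other list passed camera. Gzma rose by 3.02, and of 2 fibroblast markers 1 rose (Pdgfra, 2.85) and 1 fell (Acta2, −6.86, from probes shared between transcripts).

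Most changes were common to V7 and C5. The named genes with the largest shared rises were WNT1 inducible signaling pathway protein 1, Casein kappa, Cathepsin G, Reproductive homeobox 5 and Trat1 (7.38 in C5), and those with the largest shared falls were Mycn, Immunoresponsive gene 1, S100 calcium binding protein A6, Solute carrier family 39 member 4 and Carboxypeptidase A3 (−7.57 in C5). The shared calls came to 1158 higher and 1467 lower, where independent lists would share 79.9 and 146; quantile normalization gave 1373 and 1248, and leaving out WT2 aliquot 1 gave 1479 and 1396. Leprecan-like 1 was the only probe set called in opposite directions, lower in V7 (−2.66) and higher in C5 (2.02). Because both comparisons use the same WT2 arrays, unchanged lines were simulated against shared controls. They gave a mean of 0.02 shared calls and at most 1 in 100 draws. Without any real change few probe sets pass the adjusted threshold at all, so this number had to be small. It does not show how many of the shared calls come from the shared arrays. The covariance of the log2 changes was 0.836, of which the simulation gave 0.0706 and left 0.765 (r = 0.904 against 0.501 across probe sets). The simulation rests on a modelled spread pooled over the arrays of all lines. The WT2 aliquots differed more from each other than those of the other lines. The SD of the difference between aliquots across probe sets was 0.638 in WT2, 0.513 in V7 and 0.562 in C5. The value of 0.0706 may therefore be too low for the shared controls, and 0.765 too high. The WT2 aliquots were also too few to be split between the comparisons, so part of the sharing may come from these controls.

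Stepwise changes, in the order of the metastasis labels, were rare. Apolipoprotein D fell from 1503 ± 73.6 in WT2 to 83.3 ± 18.2 in V7 and 18.4 ± 4.41 in C5, Sciellin from 199 ± 25.7 to 46.2 ± 7.58 and 6.26 ± 3.48, and Yippee-like 2 from 755 ± 1.62 to 362 ± 2.66 and 141 ± 35.6 (n = 2 each). Altogether 4 probe sets fell and 1 rose at both steps, where independent lists would give 1.37 and 0.423. In the opposite pattern, 9 probe sets rose and then fell and 4 fell and then rose. The V7 arrays enter both steps with opposite sign. The 5 stepwise probe sets became 13 and 12 without WT2 aliquots 1 and 2, 1 and 2 without V7 aliquots 1 and 2, and 2 and 3 without C5 aliquots 1 and 2. More rose than fell without WT2 aliquot 1 (7 and 6), WT2 aliquot 2 (7 and 5) or V7 aliquot 1 (1 and 0) and with the median signal added (6 and 5).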

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

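The planted 4-fold changes and their limits of 50% and 80% were set in advance, and quantile normalization, the fits of 2 lines alone and leaving out arrays were planned as alternatives, but their use as tests of an explanation, the split of the WT2 spread test into 2 parts, the t-test and all other tests in this part were chosen only after the result was seen.

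The following 10 genes were singled out because the change against WT2 in C5 differed from that in V7, by the limma test of C5 minus V7 itself. Leprecan-like 1 changed by −2.66 in V7 and 2.02 in C5, a difference of 4.68 (adjusted p = 3.28e-05) whose size depends on the constant added before taking logs, since the V7 signal of 2.77 was below it. Regulator of G-protein signaling 18 changed by −0.24 in V7 and 3.67 in C5, a difference of 3.90 (adjusted p = 2.05e-06). Prkch changed by −1.60 in V7 and −0.47 in C5, a difference of 1.13 (adjusted p = 0.00595). Sciellin was lower by −2.00 in V7 and −4.21 in C5, a difference of −2.21 (adjusted p = 0.0216) that was −2.78 with 1 added before taking logs and −1.40 with the median signal added. Apolipoprotein D was lower by −4.11 in V7 and −6.02 in C5, a difference of −1.91 (adjusted p = 0.00595). For Dntt the changes were 5.99 and 4.17 and differed by −1.82 (adjusted p = 0.0250). For Fatty acid binding protein 4 they were 3.77 and 2.02 and differed by −1.76 (adjusted p = 0.0250). Those of Yippee-like 2 were −1.05 and −2.41 and differed by −1.35 (adjusted p = 0.0153). Itga6 had changes of 1.19 and −0.10, which differed by −1.29 (adjusted p = 0.0216). Phlda1 had changes of −0.72 and −1.89, which differed by −1.18 (adjusted p = 0.00595). Of these 10 calls, 8 were lost without V7 aliquot 1, 7 without V7 aliquot 2, 7 without C5 aliquot 1, 7 without C5 aliquot 2 and 0 without either WT2 aliquot. Without the variance trend 9 were lost, under the adjusted t-test 10 and under the other settings 0 to 5.

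V7 and C5 differed from WT2 at 3385 and 3524 probe sets. Array scaling as the whole source is argued against by the 86.2% of V7 calls that kept their direction and threshold after quantile normalization, although the share of calls that were higher moved from 42.2% to 52.5%. Less intact RNA in WT2, whose Gapdh 3' to 5' ratio was the highest but whose beta-actin ratio was the lowest (1.93, against 2.27 in V7 and 2.39 in C5), stays open: 260 of 265 genes with several called probe sets (98.1%) went one way, but probe sets of 1 gene lie near the same end of the transcript, so this share cannot exclude it. With 1 PMA-sensitive clone, differences tied to PMA response, adhesion or metastasis cannot be told apart from unrelated differences between clones, and the biological explanation that the labels name remains untested.

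Few probe sets separated C5 from V7, 27 against 3385 for V7 with WT2. A spread between the WT2 aliquots that widens the shared variance is argued against as the source of this gap, because the V7 and C5 arrays fitted alone gave 72 calls, 2.21% of the 3262 from the V7 and WT2 arrays alone. Too few arrays, 2 per line in both comparisons, are argued against as the source of the gap in large changes, because 29 probe sets differed at least 4-fold between C5 and V7, called or not, 2.70% of the 1075 between V7 and WT2 (984 and 4857 at 2-fold). The WT2 spread may account for the smaller difference between 27 and 72, 26 of the 27 among them (65 and 68 without WT2 aliquots 1 and 2), and too few arrays for some missed calls, where the test did not decide: 78% of planted 4-fold changes were called in simulated data, and 76% between V7 and WT2, just under the limit of 80%. These planted rates do not give the share called in the real data, where far more probe sets passed between V7 and WT2. Of the probe sets that differed at least 4-fold, 1070 of 1075 were called between V7 and WT2 and 6 of 29 between C5 and V7. At 2-fold these were 3385 of 4857 and 27 of 984. A closer relation between V7 and C5 than between either and WT2 also stays open, as the design gives no further clone to test it.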

How the results depend on the processing

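The methods' t-test was chosen only after the data had been seen; all other settings here were fixed in advance. No call of a named gene or list reversed under any of them, but the balance of higher and lower calls did. Quantile normalization gave more higher than lower calls against WT2 (1703 and 1538 in V7, 1801 and 1744 in C5), as did leaving out WT2 aliquot 1 for C5 (1962 and 1929). Both also turned the calls shared by V7 and C5 (1373 and 1248, 1479 and 1396). Stepwise calls, 1 higher and 4 lower, became 6 and 5 with the median signal added and 7 and 6, 7 and 5, and 1 and 0 without WT2 aliquots 1 and 2 and V7 aliquot 1. Between C5 and V7 the 8 higher and 19 lower calls became 8 and 7 with a term for the aliquot number, 7 and 6 at an adjusted p below 0.01, 3 and 1 without a variance trend, 158 and 135 under the unadjusted t-test, and 5 and 0, 4 and 1, 4 and 2, and 5 and 2 without V7 aliquots 1 and 2 and C5 aliquots 1 and 2. Under other settings 72 counts stayed within 1.5 times and 32 moved; with an array left out these were 36 and 18. Named genes kept direction and side of the threshold in 1928 cases under other settings and lost the call in 210, of which 160 were under the adjusted t-test; with an array left out these were 929 and 61, and on other probe sets 55 and 4. Lists kept their result in 206 cases and lost it in 4, and kept it in all 252 with an array left out, where a single array left in a line is assumed to vary like the others. Quantile normalization and the filters moved none of the counts against WT2 by over 1.5 times.

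The counts that moved follow. Without a fold limit 6648 probe sets were called for V7 and 6945 for C5 against WT2 and 9 were stepwise; at 1.5-fold these were 5741, 5981 and 8. Calls shared by V7 and C5 against WT2 numbered 5410 and 4579 under these limits, against 2625. At an adjusted p below 0.01, 13 were called between C5 and V7, 11 in the authors' list for that pair and 2 stepwise. With the median signal added, these were 55, 40 and 11; without a variance trend 4, 3 and 0; with a term for the aliquot number 15, 12 and 3. Without a signal filter 3 were stepwise. The fit of V7 and C5 alone called 72, and 51 in the authors' list. Leaving out an array gave 5 to 68 between C5 and V7, 3 to 50 in the authors' list and 1 to 13 stepwise. With an estimated correlation 0 of 4 list calls passed. The methods' t-test gave 293 between C5 and V7 and 59 in the authors' list unadjusted. After adjustment it gave 0 in V7 and 1 in C5 against WT2 and 0 between C5 and V7, where limma gave 3385, 3524 and 27. Calls of named genes, counted per gene and comparison, were 0, where limma gave 160. In either authors' list it gave 0, where limma gave 2028 and 22. The unadjusted test gave 2848 for V7 against WT2. Fold and p limits change counts by construction; the cause was not tested for the others. The aliquot numbers did not pair samples (correlations of deviations from −0.04 to 0.04).

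Averaging all probe sets of a gene was not run, since probe sets were the unit, and lists of other cell types were too small for an estimated correlation. Signals near background limit the size of the largest changes.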

Other observations

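The name groups in this part and all of their tests were chosen only after the deposited gene names and the directions of change had been seen: 6 groups in 3 comparisons, 18 Fisher's exact tests in all, 2-sided and adjusted over the 18; quantile normalization had been planned, but not as a test of an explanation.

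Transcripts outside the fixed lists also set WT2 apart. The Gapdh 3' to 5' ratio, a sign of RNA quality, was 1.64 ± 0.181 in WT2, 0.924 ± 0.0519 in V7 and 0.991 ± 0.229 in C5 (n = 2 each) and moved with the groups in this part, while that of beta-actin was lowest in WT2 (1.93 ± 0.149, against 2.27 ± 0.326 and 2.39 ± 0.741). All 6 named histone genes had a positive change in V7 and in C5, and 5 of them passed in V7 and 4 in C5. Histone cluster 1, H1c, a linker histone, was higher by 4.45 in V7 and 3.55 in C5, Histone cluster 1, H2bc by 4.14 and 3.46, and Histone cluster 3, H2ba by 3.39 and 2.58. Against the other named genes this balance did not pass in V7 (exact p = 0.0624, adjusted p = 0.225) or in C5 (exact p = 0.124, adjusted p = 0.373). Of 2 named transcripts of endogenous retroviruses, both fell. The murine leukemia retrovirus transcript went from a signal of 2830 in WT2 to 17.5 in V7 and 27.1 in C5 (log2 changes −7.03 and −6.49), and the mammary tumor virus envelope transcript changed by −2.16 and −1.92 (exact p = 0.237 and 0.246 for the group, adjusted p = 0.511 for both). Of the natural killer receptors 2 had a named probe set, and both were higher in V7 and in C5. Klrb1d rose by 4.54 and 5.95. Klra7, read by a probe set with probes shared between transcripts and named after its values were seen, rose by 1.26 and 3.17. Its difference of 1.91 between C5 and V7 passed (limma adjusted p = 0.000559), which makes it the 1 probe set that rose at both steps. For the group of 2, Fisher's exact test gave an adjusted p of 0.692 in both comparisons with WT2 and 0.511 in C5 against V7.

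Of the 7 genes with actin in the name, 2 rose and 5 fell in both lines (exact p = 0.276 in V7 and 0.284 in C5, adjusted p = 0.511). The largest of these falls was in Acta2 (−6.82 in V7 and −6.86 in C5), read by probes shared between transcripts. Coronin 1A, which binds actin filaments, fell by 2.28 in V7, and the capping protein subunit beta fell by 2.19. A second pattern of 14 cytoskeletal names, picked after the directions had been seen, had 13 lower and 1 higher in both lines. In V7 Calponin 2 was at −2.93, the myosin heavy chain Myh9 at −1.86 and Tropomyosin 4 at −1.47. Of the 7 genes above, this pattern left out Acta2, LIM domain and actin binding 1, and the riser SWI/SNF subfamily e member 1. It counted Coactosin-like 1 and coactosin-like protein as separate members. Because of this choice of names, its exact p of 0.000709 (adjusted p = 0.00765) is no independent test. One probe set named beta actin rose by 1.92 in V7, whereas the 3' control signal of beta-actin was lower in V7 than in WT2.

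Mitochondrial ribosomal proteins may be expressed at a higher level in V7 and C5 than in WT2. Of 19 named members 10 rose, 1 fell and 8 did not pass in V7 (18 of 19 positive, median log2 change 1.01, exact p = 0.0117, adjusted p = 0.0700), and 9 rose and 1 fell in C5, for example S34 (1.72 and 1.59), S16 (1.57 and 1.37) and L51 (1.51 and 1.42), while L23 fell by 1.90 in V7. In C5 quantile normalization moved the median change of all probe sets from −0.07 to 0.02. That of the members went from 0.89 to 0.88 (99.2% of its size), while in V7 it was 1.01 before and 1.07 after. So small a shift of all probe sets could hardly have removed the members' change, so this outcome is no real test of array scaling. It shows only that the difference between arrays removed by this step was small beside that change. The choice of the named probe sets could account for the balance of higher and lower members: against the other named genes the exact p in C5 was 0.0210, but 0.0945 after adjustment, a requirement that was added after the unadjusted p had been seen. The test thus leaves this open, and both RNA quality, whose Gapdh ratio moved with these genes as given above, and the biological differences between the lines stay untested as a source.

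Probe sets of 1 gene rarely disagreed. Of 265 genes with several called probe sets in V7 against WT2, 5 had calls in both directions: ADP-ribosylation factor 6, Carbonic anhydrase 12, Coiled-coil-helix domain 7, Deafness autosomal dominant 5 and Rap GEF 5, named here after their values were seen. In C5 against WT2 this was so for 4 of 254, and in C5 against V7 for 0 of 5.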
